A study of Caenorhabditis elegans with 2 samples.

How the data were processed

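The study measured where an eGFP-tagged copy of NHR-21, a nuclear hormone receptor of Caenorhabditis elegans, was bound in the genome of L2 larvae. Whole animals of both sexes from strain OP361, which carries the tagged gene as an integrated transgene in an unc-119 mutant background, were used for chromatin immunoprecipitation and sequencing. The labels give 2 biological replicates of 1 group and a fragment size range of 150 to 350 bp. The antibody label names nhr-21, whereas the description of the samples names the eGFP fusion as the target. No control sample was among the samples analysed here.

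The deposited values were peak lists, 1 per replicate and 1 pooled over both replicates, each holding 30000 candidate intervals meant as input for a reproducibility threshold, and 1 pooled list of peaks past that threshold, called the optimal peaks. Per the text listing deposited beside the replicate lists, the intervals were called on ChIP alignments together with a control alignment. The aligner, peak caller, their settings and the reproducibility threshold are not given in the sources used here. Each interval had a signal value given by the authors' peak caller and a −log10 q-value, also as deposited by the authors. Interval starts, ends and summit offsets were deposited in bp. The signal was the authors' own value for a peak and was used only to describe and rank intervals within a list. Each candidate list held exactly 30000 intervals, so the lists ended at a fixed number and not at a level of enrichment. Every optimal peak had the highest −log10 q-value of its deposited list, so q-values did not rank the optimal peaks. Read totals are not given in the lists, so sequencing depth is unknown and intervals around shares cover counting error of peaks only.

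All positions are in ce11, which has the coordinates of WBcel235. The ce10 lists served only for counts, overlaps, the rank correlation and the X chromosome share, and no coordinates were converted. Gene models came from Ensembl release 115. A promoter window ran from 1000 bp upstream to 250 bp downstream of an annotated 5′ end of a protein-coding transcript. Many worm transcripts are trans-spliced, so an annotated 5′ end can lie downstream of the site where transcription starts. A summit in the windows of several genes counted for each of them. Positions not in a promoter window were assigned, in this order, to 5′ UTR, 3′ UTR, coding exon, noncoding exon, intron and intergenic sequence.

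Optimal peaks were compared with the 25659 other pooled candidates that overlapped none of them, by two-sided Fisher's exact tests on peaks, for promoter windows, the X chromosome, autosome arms (the outer 25% at either end) and noncoding gene classes with at least 20 genes (summit within 250 bp). Gene lists were compared by two-sided Fisher's exact tests on protein-coding genes with a candidate summit in the promoter window, for lists with at least 5 such genes. Overlap of the replicates was tested by 1000 circular shifts of the replicate 2 list within chromosomes, one-sided, with 1 bp of overlap counted as shared. All 2080 words of 6 bases, counted on both strands, were compared between the 101 bp around each summit and a 101 bp flank of the same peak centred 400 bp away, by a two-sided exact McNemar test. As a control added after seeing the data, each peak was also paired with another candidate that had the same number of G and C bases in its window, which was found for 3623 of 3647 peaks. Adjusted p-values are Benjamini-Hochberg values within each family of tests, with a threshold of 0.05. Tests over peaks or genes describe these lists. Neighbouring peaks and genes are not independent, and peaks are not replicates. Shares carry 95% Wilson intervals and odds ratios 95% exact conditional intervals.

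The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Named genes were those at the 20 strongest optimal peaks (by promoter window, or else the nearest protein-coding 5′ end), nhr-21 and unc-119, the 4 members with the strongest peak in each list past the threshold (up to 2 for lists with a lower share), 6 nuclear receptors and all heterochronic genes with a promoter peak. Noncoding genes and the GCGCAGGG word were singled out after their values were seen. The alternatives covered the genome build, the peak threshold, the overlap rule, promoter windows, the background, the word controls and leaving out each replicate in turn.

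The tests were tested on simulated data built on the real candidates and sequence. At a planted odds ratio of 2, the promoter, X chromosome and arm tests made a call in 20 of 20 draws each. With nothing planted they made 0, 0 and 1 calls in 20 draws. Gene list tests called 59 of 60 planted lists and 2 of 560 others. The planted lists were cytosolic ribosomal proteins, nuclear receptors and collagens, with 79, 152 and 78 genes with a candidate. Power for smaller lists was therefore not simulated. The lists were planted only with a raised share, at an odds ratio above 2. Power for smaller excesses and for lower shares was not simulated. Genes were drawn independently, so peaks shared by neighbouring genes were not simulated either. Word tests called 20 of 20 planted words and 0 of 2080 words between unplanted flanks. Noncoding class tests made 0 calls in 100 tests on random draws. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.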

Results

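Binding of eGFP-tagged NHR-21 was mapped by ChIP-seq in whole L2 larvae in 2 biological replicates. The pooled data held 3647 optimal peaks at 3627 distinct positions, since 20 entries repeated the coordinates of another with a separate summit. The authors' signal ranged from 52.2 to 1244 over these peaks, with a median of 87.3. The optimal peaks were exactly the 3647 pooled candidates with the highest signal. With 1 group and no control sample, no comparison between conditions was made.

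Most of the strongest intervals lay at the same places in both replicates. The peak upstream of rpl-3, a protein of the large ribosomal subunit, ranked 1 in both lists, and those of cdc-48.1, a AAA ATPase that extracts ubiquitinated proteins, ranked 7 and 4. Of the 3647 strongest intervals of replicate 1, 2779 overlapped one of the 3647 strongest of replicate 2 (76.2%, 95% Wilson interval 74.8 to 77.6%). Shifted lists overlapped by 2.64% on average and by 4.47% at most (permutation p = 0.001, the smallest that 1000 shifts can give). Across the 3636 optimal peaks with an interval in both lists, Spearman's rho of the signal was 0.718 and Pearson's r of the log2 signal was 0.794, over peaks, which are not independent replicates. Among optimal peaks, 2729 (74.8%) overlapped one of the 3647 strongest intervals of both replicates.

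**Figure D1:**
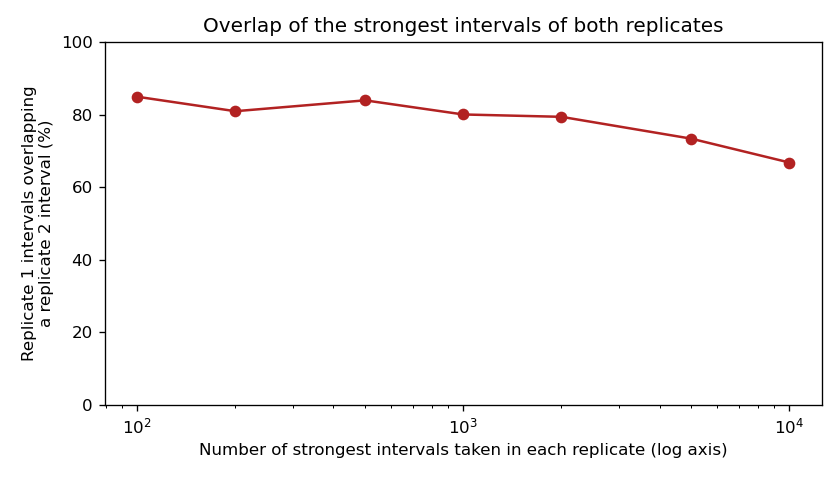
Share of the strongest replicate 1 intervals, in percent, that overlapped one of as many strongest replicate 2 intervals, against the number taken (log axis), with 1 point per number. The share was 85.0% for the 100 strongest and 66.8% for the 10000 strongest.

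Of the 20 strongest peaks, 7 lay on autosomes, all in promoter windows, and 13 on X, mostly outside promoter windows. The autosomal peaks lay in the promoter windows of rpl-3 (III:3867345-3867744, signal 1244), cdc-48.1 (II:10563419-10563732, 1002), rpl-20 and its divergent neighbour Y17G9B.5 (IV:4749917-4750237, 987), tasp-1 and K01G5.10 (III:10759088-10759427, 969), rpl-35 (III:7854545-7854847, 910), rpl-15 and K11H12.8 (IV:654772-655086, 875), and egg-5 (I:4171975-4172545, 773). On X, the promoter windows of puf-9, a Pumilio-family RNA-binding protein (X:5841061-5841502, 883), and nspc-17 (X:14525543-14526309, 803) held a summit. The other 11 X peaks were outside promoter windows. The strongest of these, at X:11093886-11094449 (signal 1105), was intergenic and had W02H3.3 as the gene with the nearest 5′ end. The next, X:13700619-13701103 (1090) and X:9465601-9466175 (974), were intergenic and nearest to K02D3.1 and ZK899.6. The peak at X:6296288-6296858 (950) lay in an intron of mom-1 and was nearest to the 5′ end of cest-16. The peak at X:8036099-8036904 (904) was intergenic and nearest to xol-1, the switch gene of sex determination and dosage compensation. The peak at X:5429328-5429797 (733) lay in a coding exon of pks-1, a polyketide synthase gene, and was nearest to C41A3.2. The remaining ones were nearest to F20B6.9, F55G7.5, Y41G9A.17, F19H6.5 and F22H10.2, with signals from 749 to 890. No measured value here tells which gene, if any, a distant peak acts on.

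Optimal peaks were concentrated upstream of protein-coding genes. Summits of 1951 peaks (53.5%, 51.9 to 55.1%) lay in a promoter window, against 32.6% of the other candidates and 27.1% of the genome (odds ratio 2.38, 2.22 to 2.55, Fisher's exact p = 3.57e-129). Coding exons held 1.78% of optimal summits against 14.7% of the others (odds ratio 0.105, adjusted exact p = 2.37e-147), and introns 13.6% against 24.7% (0.481, adjusted p = 2.33e-54). Summits in 3′ UTRs were also fewer, at 1.51% against 4.56% (0.321, adjusted exact p = 8.29e-22). Exons of noncoding genes held more, at 6.33% against 2.25% (2.94, adjusted exact p = 3.08e-35), and intergenic sequence held 22.8% against 20.8% (1.13, adjusted p = 0.00596). The share in 5′ UTRs outside promoter windows did not differ past the threshold (0.411% against 0.366%, adjusted exact p = 0.662). The median position relative to the nearest 5′ end was -206 bp for optimal peaks and 52 bp for the other candidates, with negative values upstream. In all, 2316 of the 8228 protein-coding genes with a candidate had an optimal peak in their window (28.1%). Of the promoter peaks, 507 lay in windows of several genes.

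**Figure D2:**
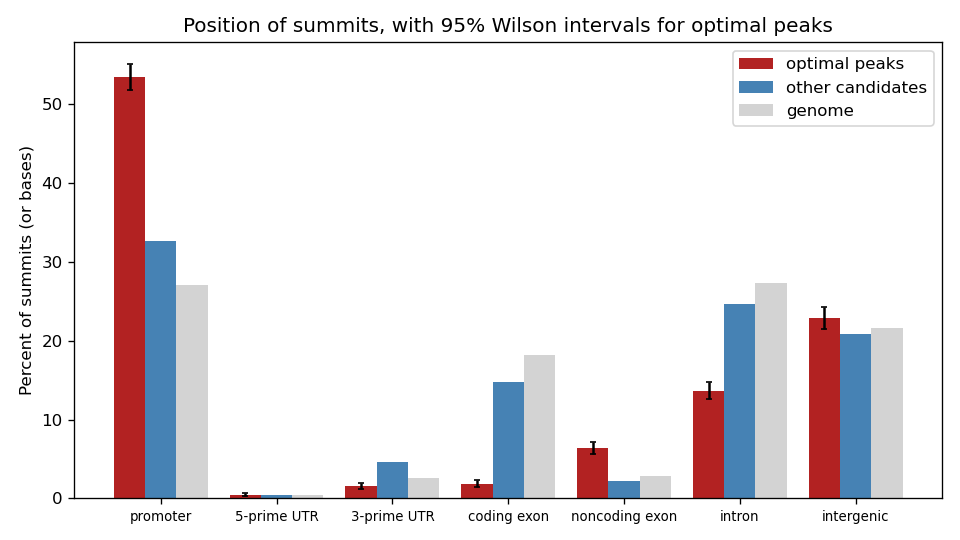
Percent of summits of optimal peaks and of other candidates, and percent of genome bases, in each annotated position, with 95% Wilson intervals on the optimal peaks. Promoter windows held 53.5% of optimal summits and 32.6% of the others, and coding exons 1.78% and 14.7%.

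The X chromosome carried more optimal peaks than autosomes. It held 814 peaks (22.3%, 45.9 per Mb) against 19.5% of the other candidates (odds ratio 1.18, 1.09 to 1.29, Fisher's exact p = 9.47e-05), while the autosomes held between 28.6 per Mb (chromosome V) and 40.3 per Mb (chromosome III). Autosome arms held 34.3% of autosomal optimal peaks and 34.8% of the other candidates, which did not differ past the threshold (odds ratio 0.978, 0.900 to 1.06, Fisher's exact p = 0.614). Without replicate 2, the strongest intervals of replicate 1 were fewer on arms (odds ratio 0.836, Fisher's exact p = 1.70e-05).

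Genes for cytosolic ribosomal proteins, heat shock proteins and chaperonin, the respiratory chain, splicing factors and translation factors had promoter peaks more often than other genes with a candidate. Aminoacyl-tRNA synthetases and mitochondrial ribosomal proteins (odds ratio 1.13) did not pass the threshold, though the latter passed with all protein-coding genes as background (odds ratio 2.25, adjusted exact p = 0.0279). Of 79 cytosolic ribosomal protein genes, 62 had one (78.5% against 27.7% of the others, odds ratio 9.54, 5.49 to 17.4, Fisher's exact adjusted p = 4.58e-19), with rpl-3, rpl-20, rpl-35 and rpl-15 strongest. Heat shock and chaperonin genes had a peak in 21 of 37 cases (odds ratio 3.37, 1.67 to 6.92, adjusted exact p = 0.00241), led by hsp-90 (signal 401), the chaperonin subunit cct-8 (391), mitochondrial hsp-60 (384) and cct-1 (373). Respiratory chain and ATP synthase genes had a peak in 29 of 56 cases (2.76, 1.58 to 4.86, adjusted exact p = 0.00241), led by cox-5A (627), atp-1 (342), cox-5B (329) and cox-6B (254). Splicing factors had a peak in 17 of 31 cases (3.11, 1.44 to 6.84, adjusted exact p = 0.0112, and 4.99 without replicate 2), with snr-4 (325), prp-40 (168) and a single peak shared by the neighbours rsp-1 and rsp-2 (191) strongest. Translation factors had a peak in 20 of 39 cases (2.70, 1.37 to 5.36, adjusted exact p = 0.0112), led by iff-2 (639), ifet-1 (619), eef-1G (412) and eef-2 (365). With all protein-coding genes as background, these odds ratios were 25.5, 4.13, 5.73, 5.93 and 7.68 in the order given. With a peak given only to its nearest gene, the calls ended for heat shock and chaperonin genes (odds ratio 1.42, adjusted exact p = 0.793), splicing factors (2.33, 0.158) and translation factors (2.65, 0.0607).

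Heterochronic genes, which set the timing of larval cell fates, had a promoter peak in 8 of 13 cases (odds ratio 4.09, 1.18 to 15.9, Fisher's exact adjusted p = 0.0470). They were lin-28 (signal 185), nhr-23 (176), lin-14 (174), myrf-1 (157), kin-20 (114), nhr-25 (97.7), lin-42 (95.7) and lin-46 (69.2). The odds ratio was 6.13 without replicate 1, 7.37 without replicate 2, 6.57 in the stronger 50% of the optimal peaks, 12.2 with all protein-coding genes as background and 27.9 with the 2000 bp window (adjusted exact p = 5.61e-05). The call ended with the 500 bp promoter window (odds ratio 2.97, adjusted exact p = 0.205) and with the nearest gene only (4.23, 0.0718). The list as fixed also named microRNA genes, which the test on protein-coding genes left out. Of 4 such genes found by name (let-7 family and lin-4), 0 had an optimal summit within 250 bp. Nuclear receptor genes, the family of NHR-21 itself, had a peak in 33 of 152 cases (21.7%, odds ratio 0.704, 0.462 to 1.05, adjusted exact p = 0.176). The direction turned without replicate 2 (1.05) and with all protein-coding genes as background (1.04). The strongest were nhr-68, a regulator of propionate breakdown (V:11572868-11573191, signal 580), nhr-34 (242), nhr-119 (222), nhr-35 (203), nhr-158 (193) and nhr-57 (192).

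Chemoreceptor genes and detoxification genes had promoter peaks less often. Of 192 chemoreceptor genes with a candidate, 21 had an optimal peak (10.9%, odds ratio 0.307, 0.185 to 0.486, Fisher's exact adjusted p = 1.20e-07), with srh-17 (signal 302) and srh-2 (301) strongest, and the odds ratio was 0.116 with all protein-coding genes as background. Cytochrome P450, UGT and GST genes had one in 11 of 76 cases (0.429, 0.204 to 0.822, adjusted exact p = 0.0300), with gst-27 (152) and gst-20 (116) strongest. This second call ended without replicate 2 (odds ratio 0.486, adjusted exact p = 0.0686), in the stronger 50% of the optimal peaks (0.392, 0.123), with the 500 bp window (0.463, 0.105) and with the nearest gene only (0.532, 0.158). Reads of near-identical family members cannot be assigned with certainty, and the authors' treatment of such reads is not given in the sources used here.

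The other lists did not pass the threshold. Intestine markers had a peak in 0 of 13 cases (adjusted exact p = 0.0796) and body wall muscle markers in 0 of 11 (0.107), while neuropeptide genes had one in 6 of 44 (0.0828). Vacuolar ATPase genes had a peak in 9 of 16 cases (odds ratio 3.29, adjusted exact p = 0.0750) and proteasome genes in 13 of 30 (1.96, 0.165). Vacuolar ATPase genes passed the threshold without replicate 1 (odds ratio 4.91, adjusted exact p = 0.0198), without replicate 2 (3.45, 0.0399), with the 2000 bp window (3.48, 0.0243) and with all protein-coding genes as background (5.74, 9.45e-04). Proteasome genes passed without replicate 1 (odds ratio 2.56, adjusted exact p = 0.0430), without replicate 2 (3.46, 0.00723), with the nearest gene only (3.63, 0.0353) and with all protein-coding genes as background (4.98, 1.40e-04). Homeobox ceh genes had a peak in 2 of 21 cases (odds ratio 0.268, adjusted exact p = 0.176), and passed without replicate 2 (0.196, 0.0399). Intestine markers passed without replicate 1 (0.0468). Collagens had one in 26 of 78 cases (odds ratio 1.28, adjusted exact p = 0.484), but had an odds ratio of 0.222 in the stronger 50% of the optimal peaks (adjusted exact p = 0.00903). Histones had one in 11 of 25 cases (adjusted exact p = 0.224), epidermis and seam markers in 9 of 21 (0.268), insulin-like peptides in 2 of 15 (0.425) and hedgehog-related genes in 4 of 24 (0.425). Fatty acid metabolism genes had one in 12 of 54 cases (adjusted exact p = 0.516), C-type lectins in 4 of 22 (0.516), daf genes in 4 of 21 (0.628) and F-box genes in 9 of 41 (0.628). Aminoacyl-tRNA synthetases had one in 8 of 25 cases (0.807), germline markers in 2 of 6 (0.807), mitochondrial ribosomal proteins in 15 of 49 (0.838), glycolysis genes in 5 of 16 (0.838) and GATA, T-box and bHLH factors in 5 of 16 (0.838). Neuron markers had one in 5 of 20 cases and actins and tubulins in 4 of 14 (both 1). Vitellogenins, pharynx markers, major sperm proteins and cuticlins had 1, 0, 1 and 4 genes with a candidate, none with an optimal peak, and were not tested. Of 35 lists, 31 were tested and 8 passed. All adjusted p-values in this paragraph are from Fisher's exact tests.

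**Figure D3:**
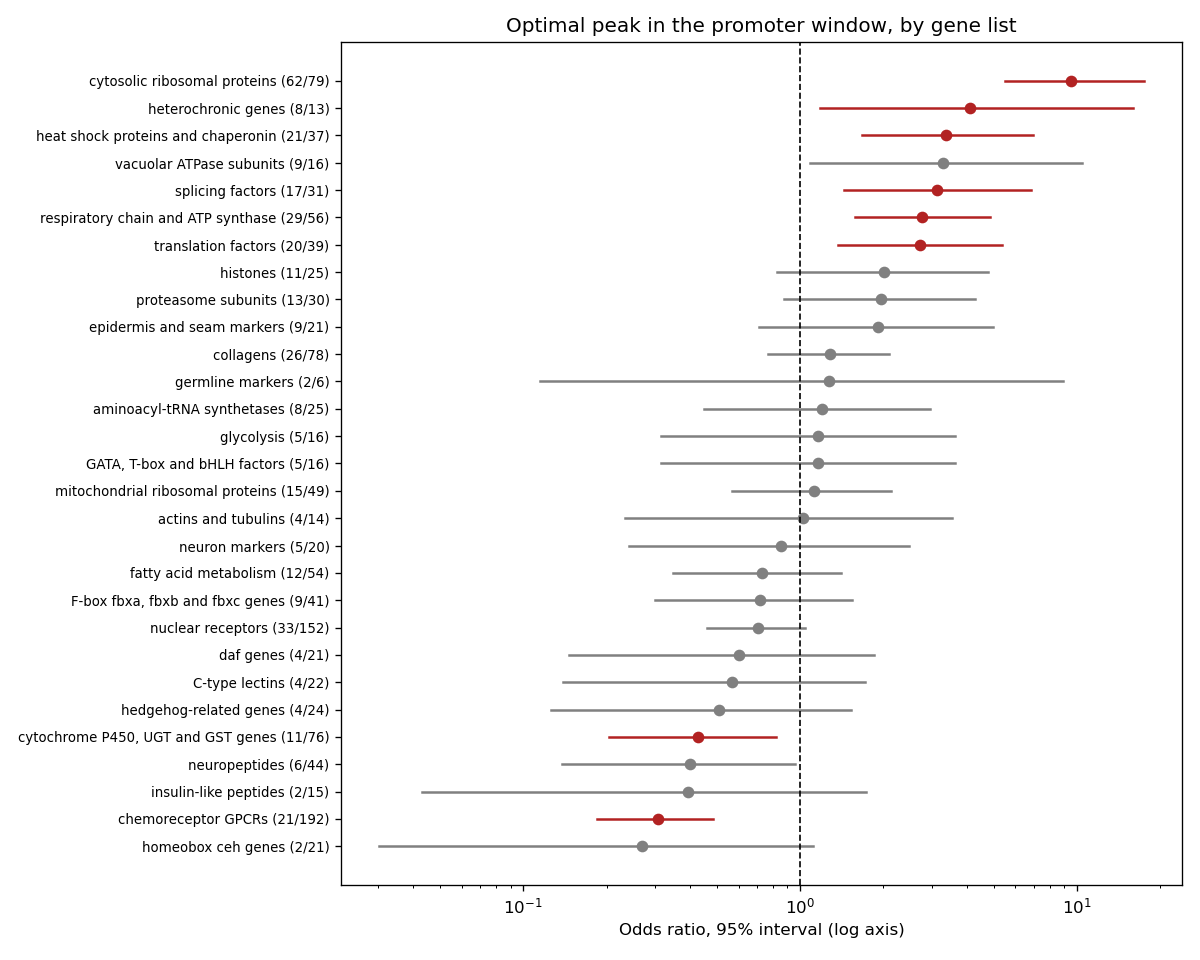
Odds ratio of an optimal peak in the promoter window for each tested gene list with at least 1 such gene (log axis), with 95% intervals and, in parentheses, genes with an optimal peak over genes with a candidate. Lists past the adjusted threshold are red, with cytosolic ribosomal proteins highest at 9.54 and chemoreceptor genes lowest of these at 0.307. The intestine and body wall muscle lists, at 0, are left out.

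Genes for tRNAs, snoRNAs and snRNAs were found beside optimal peaks more often than beside other candidates. Genes for tRNAs lay within 250 bp of 195 summits (5.35% against 0.877%, odds ratio 6.38, 5.23 to 7.80, Fisher's exact adjusted p = 2.84e-66), for snoRNAs of 100 (2.74% against 0.335%, 8.38, 6.21 to 11.3, adjusted p = 1.74e-41) and for snRNAs, which include the spliced leader RNAs, of 40 (against 0.101% of the others, 10.9, 6.50 to 18.7, adjusted p = 7.74e-20). In the stronger 50% of the optimal peaks the odds ratio for tRNA genes was 3.40 (adjusted exact p = 6.24e-17). The broad ncRNA class was higher at 17.2% against 5.88% (3.33, adjusted exact p = 1.69e-104), as were lincRNA (2.02, adjusted p = 0.00422) and miRNA genes (1.87, adjusted p = 0.0388). Genes for piRNAs were lower (1.40% against 2.65%, 0.522, adjusted exact p = 3.28e-06). Pseudogenes (0.682, adjusted exact p = 0.0981), antisense RNA genes (0.929, adjusted p = 1) and rRNA genes (0 of either set) did not pass. Without replicate 1 the miRNA call ended at about the same odds ratio (1.82, adjusted exact p = 0.0603), while within 100 bp (1.21, 0.794) and in the stronger 50% of the optimal peaks (1.41, 0.495) it ended at a lower one. Without replicate 1 or replicate 2, pseudogenes passed as a lower class (odds ratios 0.535 and 0.462, adjusted exact p = 0.00490 and 1.58e-04). No control sample or other tagged factor was analysed. Whether peaks beside these genes, or at the gene lists above, would be recovered in any immunoprecipitation was therefore not tested.

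Words rich in G and C were more frequent at summits than in flanks. Of all words of 6 bases, 748 were more frequent and 480 less frequent in the window around the summit than in the flank of the same peak (exact McNemar test, adjusted p under the threshold). The GC content was 44.5% ± 8.21 (SD over 3647 peaks) at the summit and 35.4% ± 8.64 in the flank. Words that were higher averaged 63.7% GC and those that were lower 30.1%. The highest ratios were those of CGCGCG (8.89, 160 against 18 peaks), ACGCAG (8.52), GCGCGC (8.28), ACGCGC (6.40), CGGCCG (6.33) and AGACGC (6.22). Without replicate 2, the ratios of CGGCCG and AGACGC against the flanks fell to 2.70 and 4.08. Against candidates matched for GC content, a control chosen after seeing the data, the ratios of the 6 words were 1.57, 2.06, 1.76, 2.42, 1.57 and 1.75. Among words fixed in advance, GAGAGA occurred at 24.3% of summits against 5.87% of flanks (ratio 4.14, exact McNemar adjusted p = 1.74e-106), CACGTG, the E-box, at 7.21% against 1.51% (4.78, adjusted p = 6.82e-33) and CCGCCC at 5.51% against 1.56% (3.53, adjusted p = 1.85e-19). TATAAA was less frequent (5.92% against 11.5%, 0.513, adjusted exact p = 4.71e-16). Against the GC-matched candidates, GAGAGA kept a ratio of 1.69 and CACGTG of 1.91, while the calls ended for CCGCCC (1.03, adjusted exact p = 0.927) and TATAAA (1.04, 0.855). AGGTCA, a half-site bound by many nuclear receptors, occurred at 3.76% of summits against 2.71% of flanks (1.38, adjusted exact p = 0.0266), and AAGTCA at 3.92% against 4.99% (0.786, adjusted p = 0.0513). AAGTCA passed as less frequent in the stronger 50% of peaks (0.587, adjusted exact p = 0.00388), without replicate 2 (0.782, 0.0469), with the opposite flank (0.773, 0.0332) and against the other candidates (0.829, 0.0444), but not against the GC-matched candidates (1.04, 0.878). TGATAA, a GATA factor site, had a ratio of 1.31 (adjusted exact p = 2.20e-04) and TGACTC of 0.991 (adjusted p = 1). The TGATAA call ended without replicate 2 (ratio 1.13, adjusted exact p = 0.125), in the stronger 50% of peaks (1.09, 0.522), with the opposite flank (1.16, 0.0560) and against the other candidates (1.01, 0.902). Against the GC-matched candidates it held (1.39, adjusted exact p = 3.33e-05). The AGGTCA call ended in the stronger 50% (ratio 1.42, adjusted exact p = 0.136) and against the GC-matched candidates (1.03, 0.938). In all, 261 words were higher and 342 lower than in the GC-matched candidates.

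The tagged gene itself lay in a region without intervals. The nhr-21 gene (II:7339229-7349133, plus strand) and 20 kb on either side held 0 candidates in the pooled list and 0 in each replicate list, whereas the median protein-coding gene had 12 in the pooled list. Among 9596 genes in the middle of autosomes the median was 15, and 1.13% had as few, against 4.88% of all protein-coding genes. With 10 kb on either side, 4.78% of the middle genes and 12.1% of all had as few as nhr-21, which was 0. Pooled summits were missing between 7314495 and 7373069 on chromosome II (58.6 kb), and 40 kb on either side of the gene held 13 candidates. At unc-119 (III:10902641-10908935), the gene mutated in the strain and also the rescue marker in the strain name, there was 1 optimal peak (III:10903250-10903639, signal 61.4, rank 2939). Its interval ranked 5813 in replicate 1 and 2636 in replicate 2. The unc-119 gene and 20 kb on either side held 8 candidates in the pooled list, 12 in replicate 1 and 7 in replicate 2.

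**Figure D4:**
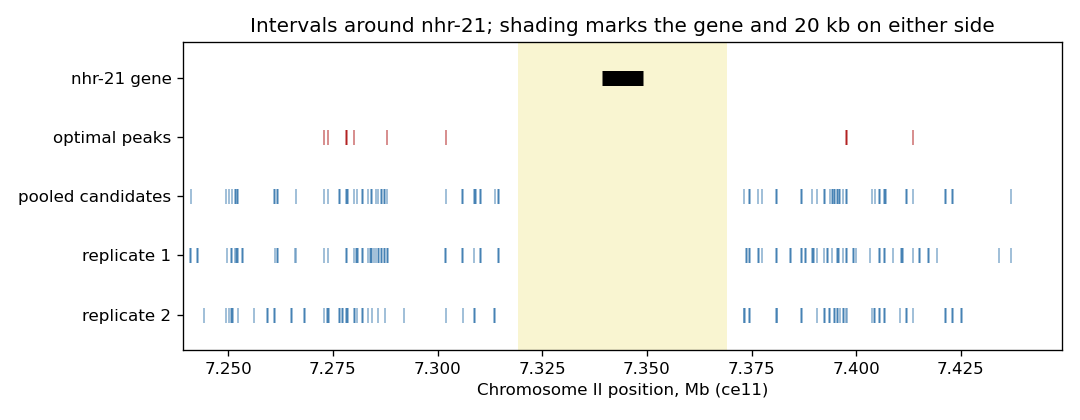
Positions of optimal peaks, pooled candidates and replicate intervals, each as a bar, around the nhr-21 gene on chromosome II (position in Mb, ce11). The shaded span, the gene with 20 kb on either side, holds 0 intervals in each list.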

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

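The comparison with GC-matched candidates and the counts at nhr-21 without either replicate were chosen after the results were seen. No paired analysis was possible because there was 1 group of samples. Of the 3647 optimal peaks, 2729 overlapped one of the 3647 strongest intervals of both replicates. Replicate overlap, promoter share, X chromosome odds ratio and noncoding class count kept their direction and their side of the threshold, or stayed close in number, under every alternative run for them. The promoter share ranged from 41.7% to 67.3% with the promoter window. Taking the 3647 strongest pooled candidates returned the optimal peaks themselves and so tested nothing. It gave 760 higher words because the side of each flank was drawn anew.

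The rank correlation was 0.747 in the stronger 50% of the optimal peaks. The chromosome arm odds ratio ranged from 0.836 to 0.963 when either replicate was left out and was 1.01 in the stronger 50%. With all protein-coding genes as background 14 gene lists passed, among them C-type lectins, F-box genes, epidermis and seam markers and mitochondrial ribosomal proteins, and with the nearest gene only 4 passed, of which 3 were among the 8 of the main setting. Against GC-matched candidates 261 words were higher in place of 748 and 342 lower in place of 480, and the ratios of TATAAA and AAGTCA turned from 0.513 and 0.786 to 1.04 each. Within 40 kb of nhr-21 there were 13 candidates in place of 0, since the wider span reaches past the gap. For the others the cause was not tested. Of 301 odds ratios of lists and classes under alternatives, 243 kept their direction and side of the threshold, 12 were weaker, 16 stronger and 30 reversed. The 243 include those with the 3647 strongest pooled candidates, which could not differ from the main setting. The ranks of named peaks with 1 replicate left out were within the 3647 strongest except for the peak at unc-119, which ranked 5813 without replicate 2. Depth is unknown, so weak peaks missed for lack of reads cannot be separated from unbound sites.

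Apart from collagens, the odds ratios that changed direction passed the threshold in neither setting. In the stronger 50% of the optimal peaks they were 0.222 for collagens, 0.934 for mitochondrial ribosomal proteins, 0.233 for aminoacyl-tRNA synthetases, 0.589 for epidermis and seam markers, 0.431 for actins and tubulins, 0.800 for glycolysis and 1.39 for antisense RNA genes. With the 500 bp window they were 0.824 for aminoacyl-tRNA synthetases, 1.24 for neuron markers, 0.824 for actins and tubulins and 0.989 for glycolysis, and with the 2000 bp window 0.661 for germline markers. With all protein-coding genes as background they were 1.04 for nuclear receptors, 1.36 for neuron markers, 0.544 for germline markers, 1.19 for fatty acid metabolism, 1.39 for daf genes and 0.645 for GATA, T-box and bHLH factors. With the nearest gene only they were 1.00 for neuron markers and 0.904 for actins and tubulins. Antisense RNA genes had 1.06 within 100 bp and 1.33 within 500 bp. With either replicate left out, the range was 0.814 to 1.05 for nuclear receptors, 0.905 to 1.07 for mitochondrial ribosomal proteins, 0.688 to 1.63 for germline markers, 0.516 to 1.02 for daf genes, 0.826 to 1.51 for actins and tubulins, 0.765 to 1.25 for GATA, T-box and bHLH factors, 0.688 to 2.38 for glycolysis and 0.930 to 1.55 for antisense RNA genes. The ratio of TGACTC was 1.05 to 1.08 with either replicate left out, 1.07 with the opposite flank and 1.03 against the other candidates.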

Other observations

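Except for the masked bases near nhr-21 and the comparison of counts around it with all genes, the tests in this part were chosen after the result was seen, as were the restriction to the middle of autosomes and the bound on the shares. A first test on X, which divided its signals by the ratio of medians, was dropped because it left 13 of the 20 strongest peaks on X. Spliced leader genes of the SL2 type, whose RNAs are trans-spliced to downstream genes of operons, stood beside some of the strongest peaks. Of 18 sls-2 genes, 14 had an optimal summit within 250 bp, led by sls-2.4 (I:4171975-4172545, signal 773, ranks 17 and 19 in replicates 1 and 2), sls-2.2 (II:5543410-5543753, 664) and sls-2.1 (II:5844619-5845184, 655). The peak at sls-2.4 is the one in the promoter window of egg-5. Of 12 sls-1 genes, which lie in repeated 5S ribosomal DNA, 0 had one, and reads of such copies cannot be placed with certainty. Of 612 tRNA genes, 223 (36.4%) had an optimal summit within 250 bp, of 346 snoRNA genes 92 (26.6%) and of 129 snRNA genes 30 (23.3%). The strongest peak beside a lincRNA gene was at linc-128 (V:1151308-1151680, signal 702). These counts were not tested beyond the class comparison.

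Of the 20 strongest optimal peaks, 13 lay on X (odds ratio 6.55, 2.42 to 19.4, against the other optimal peaks, Fisher's exact p = 4.97e-05). A uniformly higher signal on X could not be decided. The median over pooled X candidates was 1.02 times that of autosomes. The list ended at a fixed number of intervals, so a common factor could add X intervals and leave this ratio almost unchanged. The factor of 1.33 needed to bring X to 8 of the 20 left X with 16.9% (15.7 to 18.2%) of the 3647 strongest candidates. This was below the 19.5% of the other candidates, but that share was not scaled by the factor, and X is 17.7% of the genome. Sites with the word GCGCAGGG, the core of a motif at which the dosage compensation complex is recruited to X, stay open as a partial explanation. Of the 13 X peaks among the 20 strongest, where the word was first seen, 8 held it within 100 bp of the summit. The word was at 9 of 22 X peaks among the 50 strongest, 11 of 34 among the 100 strongest and 12 of 80 among the 364 strongest. After the 20 strongest, GCGCAGGG was more common on X, at 14 of 801 X peaks and 3 of 2826 autosomal peaks (odds ratio 16.7, 4.65 to 91.0, exact p = 2.07e-07). For a motif of X this excess was likely whatever NHR-21 binds, and it does not bear on peak strength. In all, 22 of 814 optimal X peaks (2.70%) held the word. Their median signal was 353 against 87.8 for X peaks without it, with the peaks where it was first seen included. On autosomes the 3 peaks with the word had a median of 90.7 against 86.5. Whether NHR-21 binds there or such sites are recovered in any immunoprecipitation was not tested, and no biological explanation was tested by the design, which has 1 group.

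The gap in candidate intervals around nhr-21 may be chance spacing. Among genes in the middle of autosomes 1.13% had as few within 20 kb, against 4.88% of all. Within 10 kb the shares were 4.78% and 12.1%. The span of 40 kb on either side reaches past the gap and held 13 pooled candidates. Its shares of genes with as few as 13, 9.16% and 24.3%, do not bear on the gap. In replicate 1 alone the shares at 20 kb were 0.448% and 1.80%. The pooled gap ranked 16 among 15716 gaps in the middle of autosomes (5 of 14927 in replicate 1 and 14 of 15705 in replicate 2). Among all 29994 gaps of each list it ranked 76 in the pooled list, 24 in replicate 1 and 67 in replicate 2. Chance spacing would thus be rare but is not excluded. Masked repeats are argued against, with 26.3% of bases soft-masked in the gap, below the median of 28.8% and the 95th percentile of 39.2% of windows of the same length. Extra copies of the tagged gene in the control alignment could raise the background there. The gap was common to both replicates over 58.6 kb, which both the transgene and a region left out by the authors would give, so these cannot be told apart without the control, which was not used here.

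The words enriched at summits may reflect base composition in part. Against candidates with the same GC content, AGGTCA had a ratio of 1.03 (adjusted exact p = 0.938), so its excess over the flanks may come from composition. This ratio cannot decide it, because the matched candidates came from the same experiment. They may include weaker bound sites that carry the same word. GAGAGA kept a ratio of 1.69 (adjusted exact p = 4.93e-25), which argues against GC content as its whole cause. Only the number of G and C bases was matched. The order of bases and the position relative to genes were not. No biological explanation was tested for either word.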
